A study of Mus musculus with 4 samples.

How the data were processed

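Kidney RNA of Th3 and control mice was compared on 4 two-colour Agilent arrays of design 014868, with 1 Th3 and 1 control sample on each. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, amplified linearly from an oligo-dT primer carrying a T7 promoter, and labelled as cRNA. Each sample's group and dye were taken from the labels: Th3 was in Cy5 on 2 arrays and in Cy3 on 2, and the 4 arrays form 1 group of ratios. Arrays are numbered as the labels number the hybridisations.

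The scanner files hold, per the file headers, spot and local background intensities from Agilent Feature Extraction 9.5.3.1, which were not normalized. They also hold processed intensities that were background-subtracted, detrended and dye-normalized by linear and LOWESS steps, per the file headers. The log10 ratio of processed Cy5 over Cy3 is per the file headers as well, and served to check the direction of each ratio. Flags for spots well above background, for outliers and for saturation are those of the deposited scanner files. The authors deposited a combined table with a log2 ratio of Th3 over control per array, whose normalization is not given in the sources used here; from the values, arrays 3 and 4 were already turned. The same table holds a signed fold, a score made by the authors by a rule that the sources used here do not give, and an adjusted p-value of the authors' test, which the sources used here do not name. Other deposited tables hold copies or selections of the combined one and were not used. The array annotation is on mouse build mm8, and every position given is from it.

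Signals were read with R 4.3.3, limma 3.58.1 and the package data.table in version 1.17.8. Mean spot signals were corrected with normexp on the local background median (offset 50) and normalized within each array by loess (span 0.3, 4 iterations), with control and outlier spots at weight 0. Control spots were then left out and outlier spots set to missing, at most 186 on an array. The 43379 remaining spots were averaged to 41174 probes. A probe was kept if it was well above background in the Th3 channel on all 4 arrays or in the control channel on all 4, with a value on at least 3 arrays, which left 26434 probes. Probes were named by accession through a RefSeq gene table of assembly GRCm38.p6, used for names only: 23374 matched by accession, 6733 by current symbol and 2919 by synonym, and 8148 kept the name in the file. The brightest kept probe stood for a gene, giving 17628 genes, 23 of them with a value on 3 arrays only. Of 6152 genes with several kept probes, 41 had probes that passed the test with opposite signs.

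Log2 ratios were fitted per gene with lmFit and eBayes on a dye term and a Th3 term, with 2 residual degrees of freedom and 4.52 prior ones, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Adjusted p-values of single genes are from this limma fit. The dye term passed the same threshold for 175 genes. A ± is the SD over arrays of the ratio turned to Th3 over control. Where no probe of a gene was well above background on any array of 1 side, which held for 9 called genes, the fold is a bound. It sets the bright side's mean against a floor per array. That floor is the higher of the lowest signal among probes well above background and the gene's own, per channel after loess and Aquantile. All 4 arrays share 1 slide and 1 scan date, so neither could be tested as a batch.

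The fit, the rule for named genes, the alternatives and 29 gene lists were chosen before the data were examined. The rule named the 12 largest increases and the 12 largest decreases among called genes with 1 sign on every array, the globin genes, and up to 2 members with the largest increase and up to 2 with the largest decrease among the called members of each list, or the member with the smallest p. Genes known only by a clone name, 5 among the increases and 2 among the decreases, were passed over. Some genes that the rule named are not reported here. The lists covered red cells, iron, hypoxia, oxidative stress, tubular injury, fibrosis, macrophages, lymphocytes, neutrophils, interferon, antigen presentation, proximal tubule, loop of Henle and distal tubule, collecting duct, podocytes, endothelium, renin-angiotensin, sex-linked and sex-biased genes, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, cell cycle, endoplasmic reticulum stress, immediate early genes, the clock, adrenal gland, adipose tissue, and pancreas and liver. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists. With an estimated correlation no list was called (0 of 29, adjusted p from 0.495 to 0.854, against 12 with the preset one).

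Most alternatives changed 1 choice at a time: the background correction, the normalization, the filter on dim probes, outlier spots, the dye term, separate channels or array weights. Others changed empirical Bayes settings or the probe rule, or left out each array in turn. Agilent's processed signals replaced background correction and normalization together. The authors' log2 ratios as deposited replaced both as well, by steps not given in the sources used here. A fit of the turned ratios with the pair of arrays of each dye orientation as a random block was added after the data were seen. The gene test was tested on simulated data for the 17628 genes of this comparison, with 50 genes changed at each of 4 sizes. It recovered 4% of the genes changed 1.2-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 11 false calls. The simulation changed 200 genes in total, far fewer than the 3793 called in the main fit. With fewer changed genes the adjustment of p-values is stricter. The recovery rates and the false calls therefore hold for the simulated data only and do not carry over to the main fit. In the simulated list test on the same genes, a list of 20 genes shifted by a log2 of 0.5 was called with the preset correlation and not with an estimated one (adjusted p = 0.106).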

Results

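Messenger RNA was compared between kidneys of Th3 mice and control kidneys. Th3 is a mouse model of beta-thalassemia, an inherited anaemia, made by deleting the genes of the adult beta-globins, beta-major and beta-minor. The design counted 4 mutant and 4 control RNA samples, hybridised in pairs on 4 two-colour oligonucleotide arrays. The Th3 sample carried Cy5 on arrays 1 and 2 and Cy3 on arrays 3 and 4. Between 62.4% and 72.7% of the probes were well above background in a channel, and no spot was saturated. The number of arrays limits the precision of every value. The labels do not state that each sample came from its own animal, so the spread between these samples may be technical. With the dye term, p-values measure the spread within each pair of arrays of the same dye orientation. They do not measure the spread between the pairs.

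The deleted beta-globin genes were examined first, as a check of the labels. Adult beta-globin RNA in Th3 kidney stood at 8.48% of control, a log2 ratio of -3.56 ± 0.48 (SD, n = 4) for the brightest probe, and it fell on 4 of 4 arrays (adjusted p = 2.7e-06). That probe, named Hbb-b1 in the array files and Hbb-bt in current annotation, lies on chromosome 7 at 103687307 to 103687366 of mouse build mm8. The other three probes of the gene stood at between 8.04% and 14.6% of control. The labels do not state whether the Th3 mice carried 1 or both deleted chromosomes, so the level to expect is not known. Beta-major and beta-minor are nearly identical in sequence, so their probes cannot be told apart; the same holds for the alpha-globin genes. The partner chain alpha-globin, Hba-a1, fell by 0.42 ± 0.23 on the log2 scale (n = 4, adjusted p = 0.0224). With pairs of arrays as a random block, a setting chosen after the data were seen, Hba-a1 did not pass (adjusted p = 0.0638), nor did it with median centring (0.0546) or with separate channels (0.0728). The embryonic beta-like gene Hbb-y had a log2 ratio of -0.03 ± 0.12 and did not pass (adjusted p = 0.738). The embryonic genes Hba-x and Hbb-bh1 were not tested, since no probe of theirs was well above background on all 4 arrays of a channel.

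The main comparison asked which kidney transcripts differ between Th3 and control mice. Of 17628 genes tested, 1927 were higher and 1866 lower in Th3 kidney, together 21.5% of the genes. Most of these differences were small: 52 genes rose and 48 fell by at least 2-fold. In the main fit the largest increase among named genes was that of Kcnj8, a pore subunit of ATP-sensitive potassium channels. It rose 4.34-fold by its brightest probe (log2 2.12 ± 0.23, n = 4, adjusted p = 5.0e-05), and its other probe had a log2 ratio of 1.47 ± 0.29. Over the alternatives the log2 ratio of Kcnj8 went as low as 1.79. With Agilent's processed signals several named genes, Rhd (log2 3.82) and Aire (3.12) among them, lay above Kcnj8 (2.17). Chil3, a chitinase-like protein of myeloid cells, rose 4.12-fold (log2 2.04 ± 0.56), and Ahsg, the plasma protein fetuin-A, rose 3.98-fold (log2 1.99 ± 0.85). Aire, a transcription factor best known from the thymus, rose by 1.98 ± 0.51 on the log2 scale. Other large increases were those of Ankrd37, a target of hypoxia-inducible factor (HIF), by 1.86 ± 0.49, and of Depp1, a FOXO-regulated gene, by 1.80 ± 0.19. Eraf, the chaperone of free alpha-globin, rose by 1.76 ± 0.83. Slc16a3, a lactate exporter, rose by 1.51 ± 0.59, Col6a1, a collagen VI chain, by 1.43 ± 0.23, and C7, a terminal complement component, by 1.43 ± 0.28. Rbm3, a cold-inducible RNA-binding protein, had a log2 ratio of 1.46 ± 0.14 by its brightest probe, but its other, much dimmer probe had -0.36 ± 0.21 and was lower on 4 of 4 arrays.

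After beta-globin, the largest decreases among named genes in the main fit were those of Ucp1 and Kap. In the authors' deposited table Ucp1 was 14.5-fold lower, more than the brightest beta-globin probe at 13.2-fold. Ucp1, the uncoupling protein of brown fat, stood at 9.45% of control (log2 -3.40 ± 0.93, n = 4, adjusted p = 0.00156). Kap, an androgen-regulated protein of the proximal tubule, stood at 9.85% (log2 -3.34 ± 0.32, adjusted p = 0.000169). Jchain, the joining chain of polymeric antibodies, fell by 2.10 ± 1.42, the heavy-chain family Igh-VJ558 by 2.02 ± 0.84 and the light-chain gene Iglv1 by 1.68 ± 1.39; a dimmer probe of Igh-VJ558 had a log2 ratio of 0.07 ± 0.06. Slc22a30 and Slc22a26, of the organic anion transporter family, fell by 1.82 ± 0.34 and by 1.62 ± 0.09. Mup1, a major urinary protein, fell by 1.96 ± 1.47 and Dio1, an enzyme that activates thyroxine, fell by 1.62 ± 0.39. Adam5, of the ADAM protease family, and Aspg, an asparaginase, were 3.32-fold (SD of the log2 ratio 0.44) and 3.04-fold (SD 0.15) lower. A dimmer probe of Aspg had a smaller log2 ratio of -0.86 ± 0.28.

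**Figure D1:**
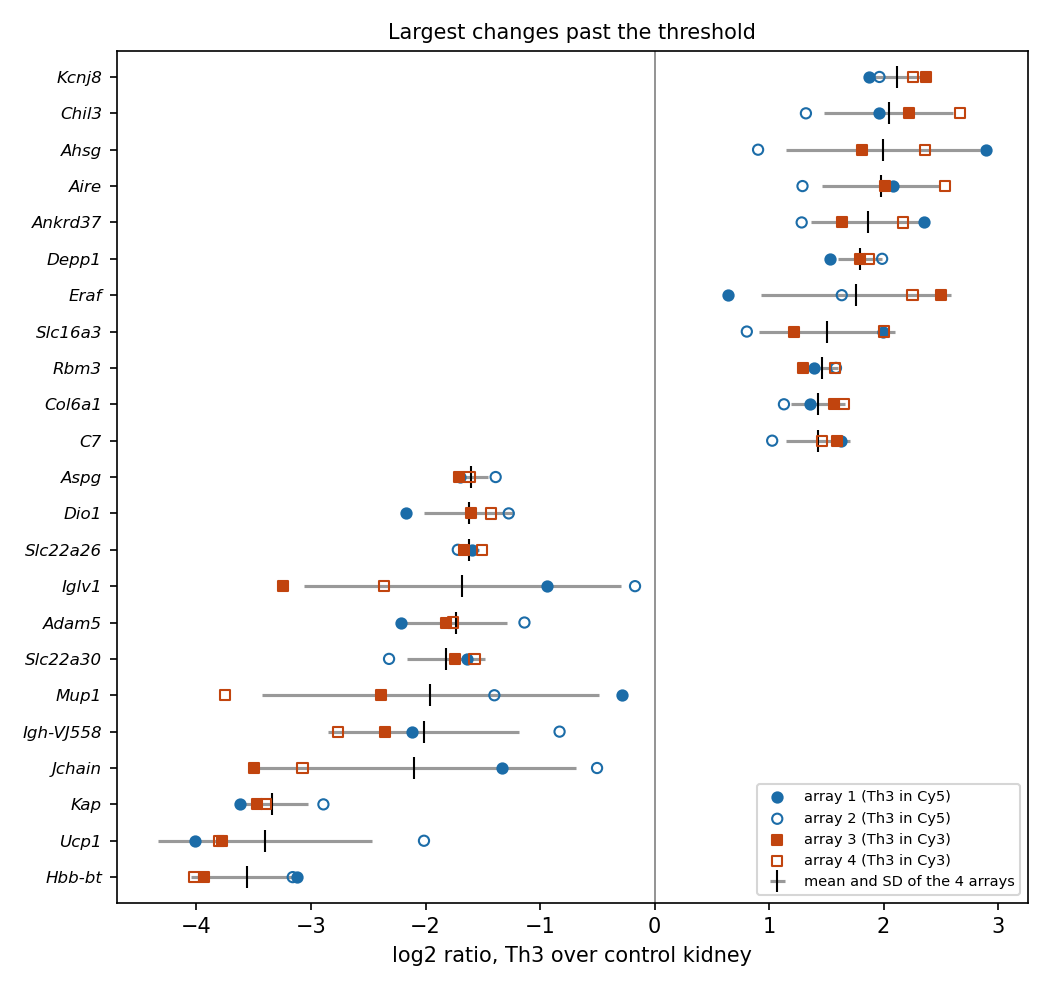
Log2 ratio of Th3 over control kidney for 11 of the largest increases and the 12 largest decreases among named genes that passed the test. Each symbol is 1 of the 4 arrays, filled or open and coloured by dye orientation, and the bar is the mean with the SD; Jchain fell by 0.50 on array 2 and fell by 3.50 on array 3, while Slc22a26 varied by an SD of 0.09.

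Genes were called with limma at an adjusted p of 0.05, with a dye term. Because the dye orientation goes with which kidneys were on the array, that term also removes any difference between the kidneys of arrays 1 and 2 and those of arrays 3 and 4; without it 1990 genes passed, all of them among the 3793, and with the pairs as a random block, a fit chosen after the data were seen, 1199 passed. Turned to Th3 over control, arrays 1 and 2 correlated at 0.67 across genes and arrays 3 and 4 at 0.71, against 0.43 to 0.53 between the pairs; genes are not independent replicates. Mup1 and Iglv1 did not pass without the dye term (adjusted p = 0.0510 and 0.0652). Ratios of dim genes depended on how the signals were processed. With Agilent's processed signals the log2 ratio was -3.30 for Adam5, 3.82 for Rhd, 2.29 for Lox and -2.34 for Cxcl9, farther from 0 than in the main fit.

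Of 35 measured genes of the HIF and hypoxia response, 22 rose, 1 fell and 12 did not pass, and adjusted over the list alone the counts were also 22 and 1. Epo, the hormone that drives red-cell production, rose 2.60-fold by its brighter probe (log2 1.38 ± 0.27, n = 4, adjusted p = 0.000993; chromosome 5, 137714833 to 137714892 of mm8), and its other probe had a log2 ratio of 2.01 ± 0.49. Ankrd37 is given above, and Pfkfb4, a regulator of glycolysis, fell by 0.31 ± 0.18. The list was higher as a set (median log2 0.39, limma's camera, adjusted p = 1.5e-08; adjusted p = 0.495 with an estimated correlation). Its median was 0.39 on arrays 1 and 2 and 0.39 on arrays 3 and 4. Pfkfb4 did not pass without the dye term (adjusted p = 0.0542), without array 1 (0.0675) or without array 3 (0.0502).

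Of 30 measured erythroid and red-cell genes, 16 rose, 3 fell and 11 did not pass; adjusted over the list alone, 19 rose and 6 fell. Eraf rose as given above, and Rhd, a blood-group protein of the red-cell membrane, had a log2 ratio of 0.94 ± 0.68 (n = 4, adjusted p = 0.00574). Its control channel was well above background on 1 of 4 arrays, and it did not pass with pairs of arrays as a random block (adjusted p = 0.0636). The decreases were those of Hbb-bt, Hba-a1 and Bpgm, the enzyme that makes the haemoglobin ligand bisphosphoglycerate, which fell by 0.30 on the log2 scale. Bpgm is named here because only 3 members fell, and was chosen after its value was seen. For Rhag, a red-cell membrane protein that rose, the control channel was not well above background on any array, which gives a bound of at least 1.21-fold. The set was higher (median log2 0.31, camera, adjusted p = 0.00164; adjusted p = 0.775 with an estimated correlation), with a median of 0.17 on arrays 1 and 2 and 0.42 on arrays 3 and 4. The call ended when only probes well above background in both channels were kept (adjusted p = 0.312) and with an intensity trend and robust variances (0.0891).

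Among 40 measured genes of iron and haem handling, 13 rose, 3 fell and 24 did not pass, with the same counts of 13 and 3 adjusted over the list alone. Hp, the haemoglobin scavenger haptoglobin, rose 2.46-fold (log2 1.30 ± 0.77, n = 4), and Hmox1, haem oxygenase, rose 2.11-fold (log2 1.08 ± 0.38). Tmprss6, a protease that restrains hepcidin, fell by 0.69 ± 0.16 and the iron importer Slc11a2 had a log2 ratio of -0.69 ± 0.28 by its brightest probe. Another probe of Slc11a2 had 0.34 ± 0.06 and was higher on 4 of 4 arrays, and the mean of its probes did not pass (adjusted p = 0.0831). The set was higher (median log2 0.08, adjusted p = 0.0176; adjusted p = 0.495 with an estimated correlation). Of 37 measured genes of oxidative stress and NRF2, 9 rose, 6 fell and 22 did not pass; adjusted over the list alone, 11 rose and 7 fell. The carbonyl reductase Cbr3 had a log2 ratio of 1.22 ± 0.34, malic enzyme Me1 -0.56 ± 0.19 and Osgin1, an oxidative stress gene, -0.47 ± 0.22. That set did not pass (median 0.01, adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation).

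Most measured macrophage and lymphocyte genes fell, mainly on arrays 3 and 4. In the dye term, which holds the difference between the pairs, camera with the preset correlation gave an adjusted p of 1.3e-17 for macrophage genes. For lymphocyte genes it gave 2.1e-09. These values depend on the preset 0.01. The dye term was not tested with an estimated correlation, which was 0.38 for macrophage and 0.46 for lymphocyte genes. Of 22 measured macrophage and myeloid genes, 1 rose, 15 fell and 6 did not pass (adjusted over the list alone, 1 and 20). The chemokine Ccl2 fell by 1.13 ± 0.73 and its receptor Ccr2 by 0.96 ± 0.48 (n = 4), while Cd163, the haemoglobin scavenger receptor, rose by 0.50 ± 0.38. Cd163 did not pass without the dye term (adjusted p = 0.0630) or without array 4 (0.0521). The set's median was -0.03 on arrays 1 and 2 and -0.80 on arrays 3 and 4 (camera, adjusted p = 1.6e-09; adjusted p = 0.495 with an estimated correlation). Of 15 measured lymphocyte genes, 11 fell and 4 did not pass, and the same 11 was the count adjusted over the list alone. Jchain is given above, and Ighm, the IgM heavy chain, fell by 1.11 ± 0.61. The lymphocyte median was -0.09 on arrays 1 and 2 and -0.73 on arrays 3 and 4 (adjusted p = 4e-07; adjusted p = 0.495 with an estimated correlation).

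All 9 antigen presentation genes that passed, of 11 measured, fell, 2 did not pass, and the count adjusted over the list alone was also 9. The class II genes H2-Aa and H2-Eb1 fell by 1.41 ± 0.68 and by 1.18 ± 0.48 (n = 4). The set's median was -0.23 on arrays 1 and 2 and -1.01 on arrays 3 and 4 (adjusted p = 3.8e-08; adjusted p = 0.495 with an estimated correlation). Of 23 measured interferon response genes, 11 fell and 12 did not pass; adjusted over the list alone, 1 rose and 12 fell. The interferon-induced chemokines Cxcl10 and Cxcl9 fell by 1.42 ± 0.65 and by 1.18 ± 0.46. The interferon median was -0.04 on arrays 1 and 2 and -0.35 on arrays 3 and 4 (adjusted p = 6.7e-05; adjusted p = 0.495 with an estimated correlation). Of 7 measured neutrophil genes, 3 rose, 1 fell and 3 did not pass (adjusted over the list alone, 4 and 2). Chil3 is given above, the calprotectin subunit S100a9 rose by 1.08 ± 0.60, and the cytokine gene Il1b, with -0.37 ± 0.25, did not pass without the dye term (adjusted p = 0.0549). The neutrophil set did not pass with camera (adjusted p = 0.191, and 0.528 with an estimated correlation). It did pass without array 1 (0.010), without array 2 (0.0412) and with an intensity trend and robust variances (0.0114). With limma's fry, which sets no list against other genes, it passed as well (adjusted p = 0.0358).

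**Figure D2:**
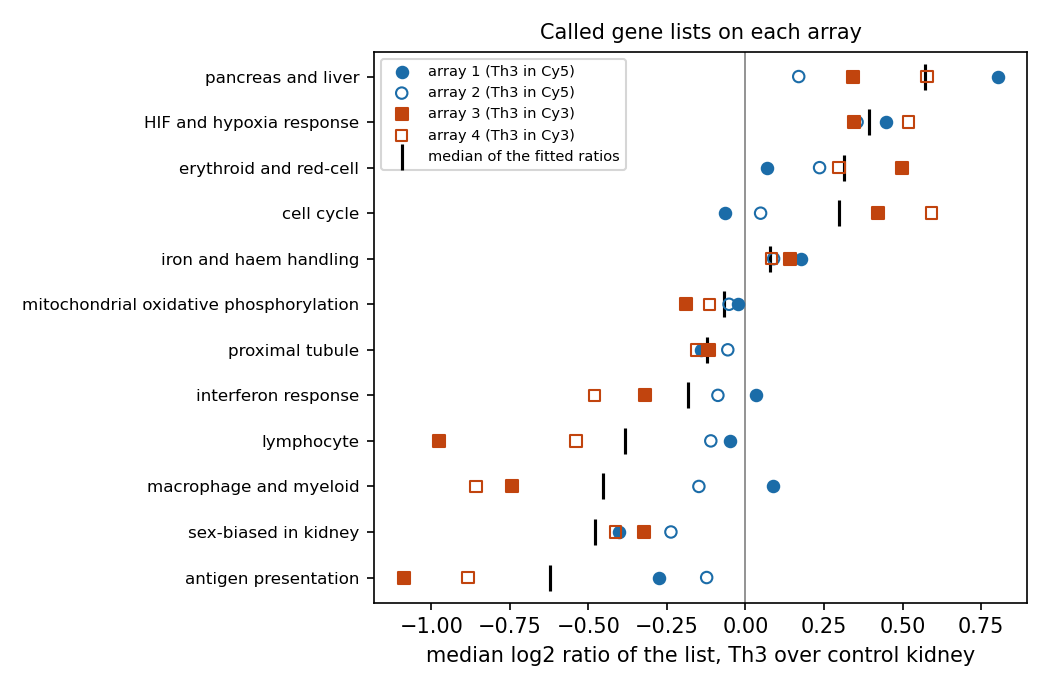
Median log2 ratio of Th3 over control kidney on each of the 4 arrays for the 12 gene lists that passed camera, with symbols by dye orientation and a bar at the median of the fitted ratios. The macrophage, lymphocyte and antigen presentation lists were lowest on arrays 3 and 4 (macrophage and myeloid medians of -0.74 and -0.86, against 0.09 and -0.15 on arrays 1 and 2), while the HIF list lay between 0.35 and 0.52 on every array.

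Of 26 measured cell cycle genes, 15 rose, none fell and 11 did not pass, and 19 rose when adjusted over the list alone. Ccnb2, a mitotic cyclin, rose 1.78-fold (log2 0.83 ± 0.58, n = 4), but did not pass with pairs of arrays as a random block (adjusted p = 0.0563). Mki67, a marker of dividing cells, had a log2 ratio of 0.56 ± 0.77 and did not pass without the dye term (adjusted p = 0.215). The set was higher with the preset correlation and not with an estimated one (camera, adjusted p = 6.2e-09 and 0.495). Its median was 0.0069 on arrays 1 and 2 and 0.45 on arrays 3 and 4, a difference held in the dye term (camera with the preset correlation, adjusted p = 1.3e-14). The dye term was not tested with an estimated correlation, which was 0.25 for this list.

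In the nephron, genes of the proximal tubule were lower as a set (median log2 -0.12, adjusted p = 0.00149; adjusted p = 0.495 with an estimated correlation). Of 33 measured, 4 rose, 14 fell and 15 did not pass (adjusted over the list alone, 4 and 16). Kap is given above, and Slc7a13, an amino acid transporter, had a log2 ratio of -1.34 ± 1.46 that ran from 0.24 on array 1 to -2.69 on array 4. Slc6a19, the neutral amino acid transporter, rose by 0.76 ± 0.34 (n = 4), and Slc13a1, the sulfate transporter, had a log2 ratio of 0.49 ± 0.35. Without the dye term, neither Slc7a13 (adjusted p = 0.128) nor Slc13a1 (0.0551) passed. Among 15 measured genes known to differ between the sexes in mouse kidney, 3 rose, 9 fell and 3 did not pass; adjusted over the list alone, 3 rose and 10 fell. Slc22a28, an organic anion transporter, fell by 1.54 ± 0.49 and Cyp4a14, a fatty acid hydroxylase, rose by 0.95 ± 0.49, while Timd2, a ferritin receptor, with 0.48 ± 0.40, did not pass without the dye term (adjusted p = 0.0782). The sex-biased set was lower (median log2 -0.48, camera, adjusted p = 0.0131, and 0.495 with an estimated correlation). Its medians were -0.45 on arrays 1 and 2 and -0.39 on arrays 3 and 4. The list was not split by which sex has more of each gene, so its direction does not point to a sex.

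Other nephron segments and the glomerulus did not pass as sets. In the loop of Henle and distal tubule, 1 of 21 measured genes rose, 5 fell and 15 did not pass (adjusted over the list alone, 1 and 6; camera, adjusted p = 0.208; adjusted p = 0.528 with an estimated correlation). Klhl3 and Pvalb, both of the distal convoluted tubule, fell by 0.58 ± 0.10 and by 0.45 ± 0.22 (n = 4). In the collecting duct, 4 of 20 rose, 1 fell and 15 did not pass (adjusted over the list alone, 5 and 1; adjusted p = 0.621; adjusted p = 0.847 with an estimated correlation). The water channel Aqp3 rose by 0.69 ± 0.15, the sodium channel subunit Scnn1a had a log2 ratio of 0.46 ± 0.35 and the ammonium transporter Rhbg one of -0.28 ± 0.07. Scnn1a did not pass without the dye term (adjusted p = 0.0670), nor Rhbg without array 1 (0.0603) or with median centring (0.114). For the collecting duct the median was -0.0025 and the mean 0.06, of opposite sign. Among 14 podocyte genes 1 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation). The decrease was that of the cell cycle inhibitor Cdkn1c, at -0.35 ± 0.37, which did not pass without the dye term (adjusted p = 0.144).

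Of 19 measured endothelial genes 3 rose, none fell and 16 did not pass, with the same count adjusted over the list alone. Vwf, von Willebrand factor, rose 2.11-fold (log2 1.08 ± 0.17, n = 4) and Flt1, a VEGF receptor, rose 1.66-fold (log2 0.73 ± 0.46), though Flt1 did not pass with pairs of arrays as a random block (adjusted p = 0.0571). The endothelial set did not pass (adjusted p = 0.208; adjusted p = 0.847 with an estimated correlation) except without array 2 (adjusted p = 0.0196). The renin genes Ren2 and Ren1, nearly identical in sequence, rose 1.80-fold (log2 0.85 ± 0.32) and 1.66-fold (log2 0.73 ± 0.04). Their probes lie side by side on chromosome 1 of mm8, at 135187713 to 135187774 and 135187628 to 135187687. The 2 increases may therefore be readings of 1 locus. Among 12 measured renin-angiotensin genes, 2 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone. As a set the renin-angiotensin genes did not pass (median -0.03, mean 0.11, adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation).

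Of 24 measured tubular injury genes, 5 rose, 6 fell and 13 did not pass (adjusted over the list alone, 7 and 8). The fibrinogen chains Fgg and Fgb rose 2.31-fold (log2 1.21 ± 0.33, n = 4) and 2.19-fold (log2 1.13 ± 0.22). Clu, the injury marker clusterin, fell by 1.01 ± 0.25 and the adhesion molecule Vcam1 by 0.70 ± 0.40 by its brightest probe. A dimmer probe of Vcam1, well above background in both channels, had -0.13 ± 0.31 and was higher on arrays 1 and 2. The set did not pass (camera direction down, median -0.0057, mean 0.02, adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation), and its median was 0.23 on arrays 1 and 2 and -0.26 on arrays 3 and 4. Of 25 genes of fibrosis and extracellular matrix, 6 rose, 10 fell and 9 did not pass (adjusted over the list alone, 6 and 12). Col6a1 is given above, the collagen cross-linking enzyme Lox rose by 0.90 ± 0.31, collagen chain Col3a1 fell by 0.99 ± 0.23 and the matrix protease Mmp2 fell by 0.91 ± 0.24. That set did not pass (adjusted p = 0.316; adjusted p = 0.847 with an estimated correlation).

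In metabolism, 6 of 34 measured genes of mitochondrial oxidative phosphorylation fell, none rose and 28 did not pass, with the same count adjusted over the list alone. Uqcrc1 and Cyc1, both of respiratory complex III, fell by 0.61 ± 0.25 and by 0.38 ± 0.02 (n = 4). The set was lower (median log2 -0.07, adjusted p = 0.0139; adjusted p = 0.495 with an estimated correlation), but its median was 0.02 with median centring (adjusted p = 0.456). The call also ended without array 2 (adjusted p = 0.0843) and with Agilent's processed signals (0.0585). Of 27 genes of peroxisome proliferator response and fatty acid oxidation, 4 rose, 4 fell and 19 did not pass (adjusted over the list alone, 6 and 4). The thioesterase Acot1 had a log2 ratio of 0.76 ± 0.47, uncoupling protein Ucp2 -0.33 ± 0.11 and the reductase Decr1 -0.30 ± 0.13. Their calls ended without array 3 for Acot1 (adjusted p = 0.0674), without array 1 for Ucp2 (0.0526), and without array 1 (0.0927) or array 4 (0.0683) for Decr1. The call of Ucp2 also ended with the mean of its probes (log2 -0.18, adjusted p = 0.0519). The set did not pass (adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation) except without array 1 (adjusted p = 0.0294).

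Of 21 cholesterol synthesis genes, 3 rose, 2 fell and 16 did not pass, with the same counts adjusted over the list alone. The enzymes Cyp51 and Mvd fell by 0.87 ± 0.41 and by 0.57 ± 0.18 (n = 4). Msmo1 had a log2 ratio of 0.37 ± 0.41 and Lss one of 0.32 ± 0.16, but the mean of the probes of Lss was -0.05. Msmo1 did not pass without the dye term (adjusted p = 0.153), without array 1 (0.0660) or without array 4 (0.0892), nor Lss without array 2 (0.0511) or array 4 (0.0608). The set did not pass (median 0.04, mean -0.0030, adjusted p = 0.636; adjusted p = 0.854 with an estimated correlation). Its median was -0.06 on arrays 1 and 2 and 0.15 on arrays 3 and 4.

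Of 21 genes of endoplasmic reticulum stress and heat shock, 1 rose, 3 fell and 17 did not pass (adjusted over the list alone, 1 and 2). The pseudokinase Trib3 had a log2 ratio of 0.30 ± 0.15, and the heat shock proteins Hsph1 and Hspb1 had ratios of -0.82 ± 0.49 and -0.49 ± 0.37 (n = 4). Their calls ended without array 3, with adjusted p = 0.0983 for Trib3, 0.0622 for Hsph1 and 0.0800 for Hspb1, without array 4 for Hsph1 (0.0674) and Hspb1 (0.1000), and without array 1 for Trib3 (0.123). Hspb1 also did not pass without the dye term (adjusted p = 0.0625). The set did not pass (adjusted p = 0.234; adjusted p = 0.854 with an estimated correlation) but did without array 1 (adjusted p = 0.000182). Of 20 immediate early genes 6 rose, 2 fell and 12 did not pass (adjusted over the list alone, 9 and 3). The orphan receptor Nr4a1 rose by 0.86 ± 0.51. The phosphatase Dusp1 had a log2 ratio of 0.76 ± 0.54 and did not pass with separate channels (adjusted p = 0.0641) or with pairs of arrays as a random block (0.0739), while the transcription factors Egr2 and Atf3, at -0.34 ± 0.28 and -0.33 ± 0.29, did not pass without the dye term (adjusted p = 0.0877 and 0.107). The immediate early set did not pass (adjusted p = 0.0833; adjusted p = 0.847 with an estimated correlation), but did without array 1 (0.00134), without array 3 (0.00582) and with no filter on dim probes (0.0440); its median was 0.30 on arrays 1 and 2 and 0.02 on arrays 3 and 4.

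Of 17 circadian clock genes, 3 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone. The transcription factor Dbp, a clock output, fell by 0.97 ± 0.52 (n = 4), and the related factors Nfil3 and Hlf rose by 0.77 ± 0.48 and by 0.52 ± 0.20, though Nfil3 did not pass with pairs of arrays as a random block (adjusted p = 0.0547). The set did not pass (median -0.06, mean 0.05, adjusted p = 0.621; adjusted p = 0.854 with an estimated correlation). Of the sex-linked genes, Xist had a log2 ratio of -0.02 ± 0.18, and Eif2s3y, on the Y chromosome, was well above background on 4 of 4 arrays in the Th3 channel and on 0 in the control channel. Eif2s3y was at least 1.27-fold higher in Th3 (measured log2 0.40 ± 0.19, adjusted p = 0.00557; log2 2.75 with Agilent's processed signals). These were the 2 measured members of that list, so 1 rose and 1 did not pass, also when adjusted over the list alone (camera, adjusted p = 0.316; adjusted p = 0.707 with an estimated correlation).

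Markers of neighbouring tissue were measured as well. None of 6 adrenal genes passed, also adjusted over the list alone, the nearest being the lipoprotein receptor Scarb1 at -0.15 ± 0.11 (adjusted p = 0.0867; set adjusted p = 0.832; adjusted p = 0.854 with an estimated correlation). Of 11 adipose genes 2 rose, 2 fell and 7 did not pass (adjusted over the list alone, 4 and 2). The fat hormone Adipoq had a log2 ratio of 1.00 ± 1.02 and the hormone Retn rose by 0.64 ± 0.35 (n = 4), whereas Ucp1 is given above and Cidea, a lipid droplet protein of brown fat, had a ratio of -1.11 ± 0.95. Adipoq and Cidea did not pass without the dye term (adjusted p = 0.110 and 0.0734). On arrays 1 to 4 the medians of the adipose list were 0.43, 0.86, 0.36 and -0.47, so array 4 alone stood apart in sign. The adipose median was 0.68 on arrays 1 and 2 and -0.07 on arrays 3 and 4; the set did not pass (adjusted p = 0.316; adjusted p = 0.854 with an estimated correlation) except without array 4 (adjusted p = 0.00546). Of 7 measured pancreas and liver genes 5 rose, none fell and 2 did not pass, and 7 rose when adjusted over the list alone. The lipoprotein gene Apoa2 had a log2 ratio of 0.66 ± 0.48 and did not pass without array 3 (adjusted p = 0.0934), without array 4 (0.116) or without the dye term (0.0523), and Ambp, a precursor of plasma proteins, rose by 0.57 ± 0.19. That set was higher (median log2 0.57, adjusted p = 0.00126; adjusted p = 0.528 with an estimated correlation), at 0.57 on arrays 1 and 2 and 0.45 on arrays 3 and 4.

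**Figure D3:**
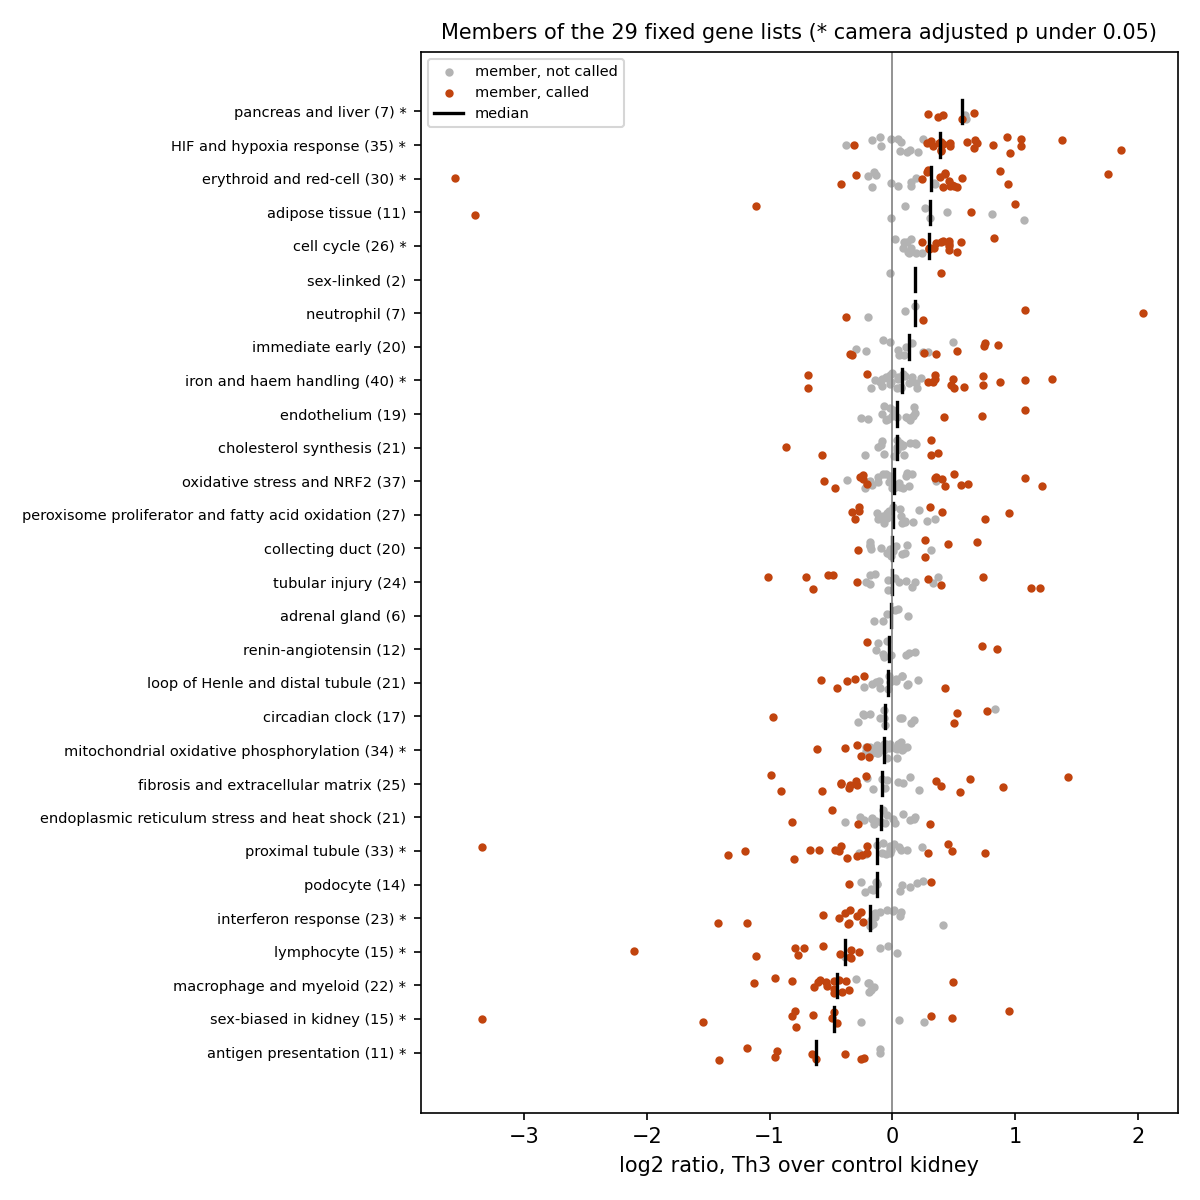
Log2 ratio of Th3 over control kidney for every measured member of the 29 gene lists fixed before the data were examined, with the number measured in brackets, a bar at the median and a star where camera's adjusted p was under 0.05 with a preset correlation. The 12 starred lists are the 5 higher and the 7 lower ones described above.

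The authors' deposited table gives a fold and an adjusted p for 37205 probes, of which 1514 higher and 1529 lower probes had an adjusted p under 0.05. Of the 17628 genes tested here, 2005 were under 0.05 in the authors' deposited table, and 1921 of these also passed here, all with the same sign. Another 1872 genes that passed here were not under 0.05 in that table. In the authors' deposited table the brightest beta-globin probe was 13.2-fold lower, Kap 10.4-fold lower, and the brighter Epo probe 3.70-fold higher.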

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

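Among the tests of this part, those of red cells of the usual kind, of the dye bias of single probes and of different RNA levels in the kidneys of the pairs of arrays were chosen only after the result was seen.

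For 6 of 129 results examined, 1 array lay far from the other three. For independent, normally distributed array values, chance alone gives about 1 in 20 such cases, 6.45 here. The arrays differ by pair and most of the genes were chosen as called ones, so that number is only a rough guide. Ucp1 had a log2 ratio of -2.01 on array 2, against -4.02 to -3.78 on the others. Mmp2 had -1.26 on array 4, against -0.83 to -0.75. Ucp2 had -0.16 on array 2, against -0.40 to -0.38. Cyc1 had -0.41 on array 2, against -0.37 on each of the others. Hspb1 had 0.054 on array 1, against -0.72 to -0.59. Dusp1 had 1.55 on array 4, against 0.38 to 0.56.

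The first pattern is the number of genes past the threshold, 3793. Turning the signs of the arrays in the other ways that the fit allows called at most 0 genes, so 1 of 7 sign patterns reached the real count, and 7 are too few for a share under 0.05. A difference in sex between the sides of the arrays cannot be told apart. Xist, bright in both channels, had a ratio of -0.02 ± 0.08 (SE), where kidneys all of 1 sex against the other would shift it far. Yet Eif2s3y, on the Y chromosome, had 0.40 near the background, under the bound set for the test, and 2.75 with Agilent's processed signals. Ddx3y, also on the Y chromosome, was too dim to be tested. Its brighter probe was well above background on 3 arrays in the Th3 channel and on 0 in the control channel. Kdm5d and Uty, also on the Y chromosome, had no probe well above background on any array of either channel. Their probes had log2 ratios from -0.07 to 0.05. The sex-biased list was not part of the test. Tissue of a neighbouring organ may contribute and cannot be told apart: the adipose median reached 0.86 on array 2, between the bounds set for the test, yet Adipoq was at 1.00 and Ucp1 at -3.40. A difference in time of day cannot be told apart either. Dbp was at -0.97, but Per1 was at 0.50 and higher on 4 arrays (limma, adjusted p = 0.0199). Nr1d1 was at -0.24, Per3 at -0.07 and Arntl at 0.83, none of which passed. Per2 was at 1.16, -1.03, -0.85 and 0.45 on arrays 1 to 4. The genotype itself stays open and was not tested against these explanations.

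The second pattern is the higher level of erythroid genes beside lower globin. More whole blood in the Th3 kidneys would raise white-cell genes too. The lymphocyte median was -0.38 ± 0.12 and the neutrophil median 0.19 ± 0.39, where ± is a bootstrap SE over the list's genes. That SE does not measure the spread between arrays, on which the lymphocyte median ran from -0.05 to -0.98. The lists went apart and this explanation stays open. More red cells of the usual kind are argued against by alpha-globin: Hba-a1 had a log2 ratio of -0.42 ± 0.09 (SE), where such cells would raise it. A candidate explanation that stays open is a different make-up of the blood or of blood-forming cells in Th3 mice, which these data do not test.

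The third pattern is the difference between arrays 1 and 2 and arrays 3 and 4. It was seen in macrophage, lymphocyte, interferon, antigen presentation, cell cycle, tubular injury, cholesterol synthesis and erythroid genes. Adipose and immediate early genes passed in the dye term too. Their medians were higher on arrays 1 and 2 than on arrays 3 and 4, but by little between the nearest arrays. On arrays 1 to 4 the adipose medians were 0.43, 0.86, 0.36 and -0.47. The immediate early medians were 0.18, 0.34, -0.12 and 0.16. A dye bias of single probes is argued against as the whole cause by probe pairs of the same gene that lie more than 200 bases apart. Their dye coefficients correlated at 0.42 ± 0.02 (SE over genes) across 5698 genes, against -0.01 after shuffling. That correlation was 0.73 of the one for the Th3 coefficients (0.58). Different RNA levels in the kidneys of the pairs may account for it. So may a dye bias shared by the probes of a gene, which this test cannot tell apart from them. Whether the difference lies in the Th3 or the control kidneys cannot be read from ratios, and no label separates the pairs other than by dye.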

How the results depend on the processing

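Beta-globin passed under all 20 alternatives, with a log2 ratio from -3.60 to -3.29. The count of called genes, 3793, was 1990 without a dye term, 5735 with separate channels and 1199 with pairs of arrays as a random block (chosen after the data were seen); all 1990 and all 1199 are among the 3793, and the cause was not tested. Leaving out 1 array, which leaves a lone array in 1 dye orientation that is assumed to vary like the rest, gave 2571 to 3190 genes, and the other alternatives by gene gave 3082 to 3875; tested 1 by 1, 4810 of 26434 probes passed. With median centring 62.9% of the calls were increases, against 50.8%. Of 100 named genes, 20 lost the call without a dye term, 32 with the random block and 13 without 1 array, all in the same direction. With Agilent's processed signals, ratios of dim genes lay farther from 0, such as 3.82 for Rhd and -3.30 for Adam5. With the mean of the gene's probes in place of the brightest, Lss turned to -0.052. Of the fixed gene lists, 12 were called, and 0 with an estimated correlation. Fry, which sets no list against other genes, called 3: antigen presentation, sex-biased and neutrophil genes. The neutrophil list is not among the 12. Several of the 12, the HIF list among them, lay just over the threshold with fry (adjusted p = 0.0501). The slide and scan date were not run as blocks, as the arrays share them. The main fit is already paired, since each ratio sets 1 Th3 sample against the 1 control sample on its array. No further pairing was possible, as no replicate numbers are shared between groups. Probes near the background limit small changes: 62.4% to 72.7% were well above it.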

Other observations

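Some liver-type plasma protein genes beyond the named ones, picked after their values were seen, were higher in Th3 kidney. Apoh, a plasma glycoprotein, had a log2 ratio of 1.09 ± 0.67 (SD, n = 4) and Hpx, the haem scavenger hemopexin, 0.87 ± 0.40, both higher on 4 of 4 arrays (limma, adjusted p = 0.0191 and 0.00913). Albumin, the most abundant liver transcript, had 0.59 ± 0.54 and did not pass (adjusted p = 0.0712), below Ahsg at 1.99.

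The fat genes here were picked after their values were seen. Cfd and Cidec, of white and brown fat alike, were higher on arrays 1 to 3 and lower on array 4, with Cfd at 2.11 on array 2 and -0.38 on array 4, and neither passed. Cox8b, a respiratory chain subunit of brown fat and muscle, fell by 1.23 ± 0.91 (n = 4, limma, adjusted p = 0.0234), on 3 of 4 arrays.

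Arntl and Per2, clock genes picked after their values were seen, changed sign between arrays. The ratio of Arntl was -0.30, 1.41, 1.67 and 0.56 on arrays 1 to 4, where Per2 had 1.16, -1.03, -0.85 and 0.45.

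No difference in the share of called genes was detected near the deleted locus. Within 10 Mb of beta-globin on chromosome 7 of mm8, 41 of 187 genes (21.9%) were called, against 3726 of 17334 elsewhere (21.5%, Fisher's exact test, 2-sided p = 0.858).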
